A study of Mus musculus with 6 samples.

How the data were processed

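Kidneys of 6 C57BL/6 mice were taken 7 days after ligation of 1 ureter, and cells of the obstructed kidney were profiled by droplet single-cell RNA sequencing on Singleron GEXSCOPE beads. Per the labels, 3 mice had received the compound SH045 and 3 its vehicle, and 6000 cells were targeted per sample. The contralateral control kidneys and the spatial samples that the series also describes were not analysed here. The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode. Per the labels the genome build was mm10, while the aligner, the counting program, the annotation and the rule for calling cells were not given in the sources used here. The deposited counts were whole numbers, and the lowest total of any barcode lay between 2166 and 3175 UMIs by library, so barcodes had been filtered before deposit.

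The 6 matrices held 25978 barcodes and 31276 genes. A barcode was kept with at least 200 genes, at least 500 UMIs and at most 50% mitochondrially encoded UMIs, which 2400 barcodes failed. The 5% of cells with the highest Scrublet score in each library were then removed (1182 cells), leaving 22396 cells. Counts were scaled to 10000 per cell and log-transformed with scanpy 1.11.5, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1.0 gave 29 clusters, of which 0 held over 80% of its cells from a single library. No integration of libraries was applied. Clusters were named from a table of markers for 26 cell classes, with at least 3 markers detected. Cells were also named singly from the same markers, and 73.6% of cells then got the class of their cluster. Cell classes of the authors were not used here, so all classes are rebuilt.

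UMI counts were summed per library, over all kept cells and over each cell class, and the 2 groups were compared with edgeR 4.0.16 (TMM factors, default low-count filter, robust quasi-likelihood test) under R 4.3.3. A class was tested where each library held at least 30 of its cells, and the Benjamini-Hochberg limit was 0.05 within each class. After the data were seen, fibroblasts, endothelium and monocytes were tested as well, at a minimum of 20 cells. Cells are not replicates, so n is the number of mice throughout. Shares of cells per class were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 is 0.1, and by edgeR on cell counts. For 29 gene lists, camera (limma 3.58.1) with a preset correlation of 0.01 was run for each list with at least 5 measured genes, adjusted over all pairs of list and class. The same pairs were run with an estimated correlation and with fry.

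Named genes followed a rule. It took Trpc6, the 5 largest rises and the 5 largest falls among called genes whose libraries did not overlap between groups, the 4 members of each called list with the smallest unadjusted p, and 12 fixed genes of fibrosis, injury and tubule function. Gene models without a symbol and sex-linked transcripts were left out of the largest changes. Genes with 0 counts in a group have a fold against a floor of 3 counts over the group, and genes with 1 to 3 counts have a ratio with an exact 95% counting interval. The samples, tests, lists, markers, naming rule and first set of alternative settings were fixed before the data were examined.

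The alternative settings fixed at that time were DESeq2 1.42.0 (its size factors, and its test), no low-count filter, a block on the replicate number, leaving out each library in turn, a mitochondrial limit of 20%, a UMI minimum of 1000, no doublet removal, Leiden resolution 2.0 (45 clusters), cells named singly, markers of other classes left out, and adjustment over all classes. No barcode had under 1000 UMIs, and markers were left out without a new fit or adjustment. Neither setting could therefore change the call of a gene, and passing them is no support. Alternatives added after the data were seen were a common minimum of 3175 UMIs for all libraries, sums over all deposited barcodes, macrophages without cluster 20, and removal of the trend on transcript length. For the last, the deviation of each library from the mean of all libraries was fitted for each class as a natural spline with 5 degrees of freedom on the log10 length of the longest annotated transcript, and taken out as an offset. Of the genes tested, at least 99.9% had a length. Tested on simulated data with the same depth and spread, the edgeR comparison recovered between 78% and 96% of genes changed 4-fold, by class, with the right direction in 100% of them, and between 21% (fibroblasts) and 72% (injured tubule) of genes changed 2-fold, with 27% in proximal tubule. Each simulation held 200 changed genes, 100 of them changed 4-fold. Unchanged genes were called as well, 14 in whole-library sums, 15 in injured tubule and 4 in endothelium. The false share of the calls was above the Benjamini-Hochberg limit in whole-library sums and injured tubule, and under it in endothelium. A simulation for cell shares drew all classes at 1 common dispersion of 0.336, not at the spread of each class, and recovered 33.3% of classes changed 4-fold. That value is therefore not the power for any single class.

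The libraries held 21186872, 24786650 and 22166608 UMIs (SH045) and 21271281, 32256602 and 26888822 UMIs (Vehicle). Intervals and floors cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used for the remaining steps.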

Results

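Single-cell RNA counts were collected from obstructed mouse kidneys 7 days after ureteral ligation, a surgical model of kidney fibrosis. The 6 libraries, each from 1 mouse, fall into SH045 (n = 3) and Vehicle (n = 3), and the total depth ranged from 21186872 to 32256602 UMIs. The series title ties the compound to inhibition of TRPC6, a calcium-permeable cation channel, so the comparison asks which cells and transcripts of the obstructed kidney differ with the compound. After filtering, 3249, 3785 and 3443 cells remained in the SH045 libraries and 3937, 4051 and 3931 in the Vehicle libraries. Median UMIs per kept cell were 4020, 4207 and 3768 with SH045 and 3498, 5350 and 4535 with Vehicle. Barcodes with over 50% mitochondrially encoded UMIs, which were left out, made up 12.4 ± 3.56% of the SH045 and 4.34 ± 0.88% of the Vehicle barcodes (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows).

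Fibroblasts and endothelial cells took larger shares of the SH045 libraries, and dendritic cells a smaller one. Fibroblasts, the main makers of scar matrix, were 3.44 ± 0.74% of SH045 cells and 0.65 ± 0.05% of Vehicle cells (SD, n = 3), a ratio of 5.25. Endothelial cells were 2.85 ± 0.50% against 0.86 ± 0.12%, a ratio of 3.30. Dendritic cells, which present antigen to T cells, were 7.0 ± 0.58% against 13.02 ± 1.29%, and were 1.86 times more frequent with Vehicle. Injured tubule cells, named from markers such as Havcr1 and Sox9, were 7.94 ± 0.53% against 5.82 ± 0.73%. In these 4 classes all SH045 libraries lay apart from all Vehicle libraries, with a two-sided exact permutation p = 0.1 and an adjusted p = 0.425 over all classes.

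The other classes overlapped between the groups. Macrophages were the largest class, at 38.99 ± 10.25% of SH045 and 45.64 ± 6.04% of Vehicle cells (SD, n = 3, exact permutation p = 0.4). T cells were 6.82 ± 2.59% against 3.84 ± 1.48%, collecting duct principal cells 7.21 ± 2.49% against 4.08 ± 1.20%, and proximal tubule cells 4.84 ± 1.90% against 8.02 ± 6.82%. Pericytes and smooth muscle cells, the other contractile stromal class, were 0.69 ± 0.23% against 0.62 ± 0.13%. All tubule classes together were 36.35 ± 7.66% against 30.67 ± 8.38%.

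With edgeR on the cell counts, fibroblasts rose by 2.39 ± 0.28 on the log2 scale (SE, adjusted p = 0.00328), endothelium rose by 1.72 ± 0.27 (adjusted p = 0.00748) and dendritic cells fell by 0.90 ± 0.22 (adjusted p = 0.0443). The fibroblast call held with any 1 library left out (adjusted p from 0.00432 to 0.0344), the endothelial call ended without Vehicle 1 (adjusted p = 0.0598, in a range from 0.0142), and the dendritic call ended without any 1 of the 6 libraries (adjusted p from 0.0649 to 0.226). With cells named singly, the injured tubule share no longer differed in the same direction (log2 ratio -0.074 in place of 0.448). A UMI of any of 6 adventitial genes was seen in 61.7 ± 14.1% of SH045 and 48.9 ± 5.58% of Vehicle fibroblasts (SD, n = 3, exact permutation p = 0.3). Of these genes, Mfap5, a microfibril protein, was seen in 155 of 361 SH045 and 23 of 78 Vehicle fibroblasts, while Clec3b, tetranectin, and Scara5, a scavenger receptor, were seen in 43 and 34 of 361 and 0 of 78 (which allows up to 3.85% of cells with a UMI, not of cells expressing them). Adipocyte markers were at 41.9, 0.121 and 44.7 CPM over all barcodes in SH045 1, 2 and 3 against 0.089 ± 0.025 with Vehicle.

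**Figure D1:**
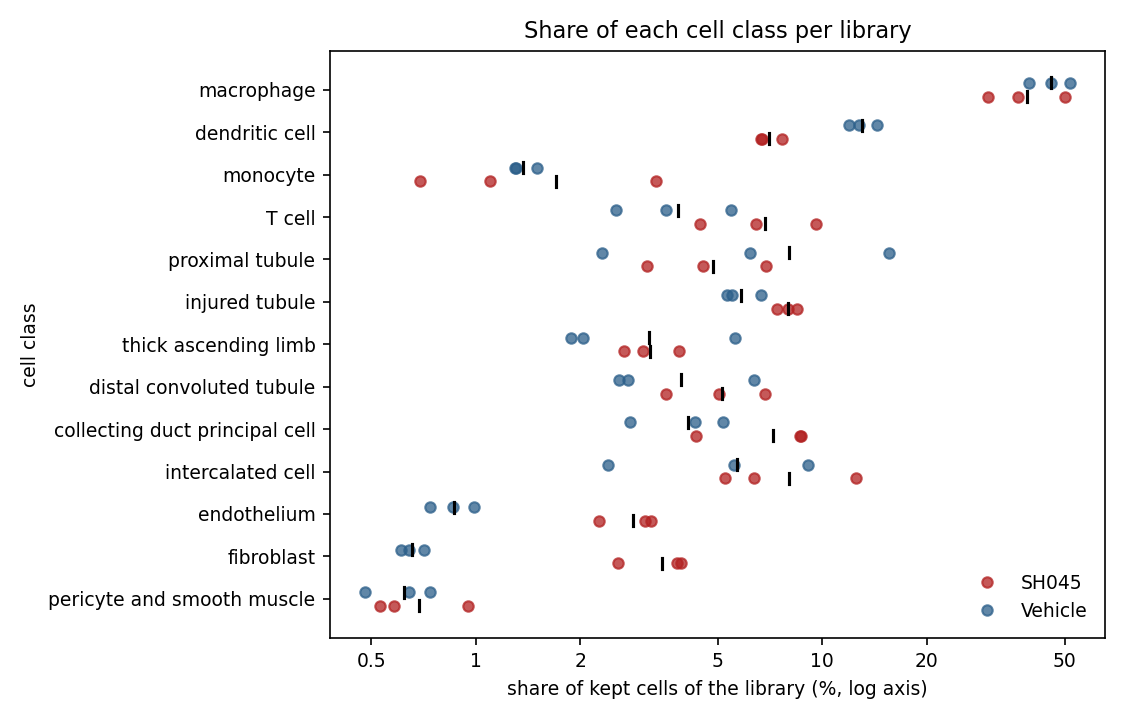
Share of kept cells in each cell class, in percent on a log axis, with 1 dot per library (n = 3 SH045, n = 3 Vehicle) and a black tick at each group mean. Fibroblast shares were 3.82, 3.91 and 2.58% with SH045 and 0.61, 0.64 and 0.71% with Vehicle.

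Trpc6 itself (ENSMUSG00000031997, chromosome 9, 8544142 to 8680741, plus strand, mm10) gave 29 UMIs in 20 of 22396 cells, of which 17 were fibroblasts (17 of 439, 3.87%, exact Clopper-Pearson 95% interval 2.27 to 6.13%, median depth 5665 UMIs) and 2 were pericytes or smooth muscle cells (2 of 145, 1.38%, interval 0.167 to 4.89%). Macrophages, taken as a class that should lack the gene, had a UMI in 1 of 9527 cells (0.01%, median depth 3556 UMIs). The endothelium gave 0 of 399 cells, which allows up to 0.752% of cells with a UMI, and the injured tubule 0 of 1524, which allows up to 0.197%. These limits concern detection at the depth of the libraries and do not exclude expression in those classes. The gene was under the count filter of every class, so no difference between the groups was tested.

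Before the genes of each class, a property of the libraries is given because it moves with the groups. In the whole-library sums, log2 changes across genes correlated with transcript length (Spearman 0.434 over 16373 genes, which are not independent replicates). The median change was -0.20 among the 10% of genes with the shortest transcripts and 0.37 among the 10% with the longest. The same correlation was 0.454 in macrophages, 0.441 in injured tubule, 0.422 in collecting duct principal cells, 0.429 in intercalated cells, 0.554 in distal convoluted tubule and 0.275 in proximal tubule. It was 0.213 in fibroblasts and 0.24 in monocytes. Taken library by library, the correlation with length lay apart between the groups in all tested classes but proximal tubule and fibroblasts, where they overlapped. Counts of called genes per class are given below also with this trend removed per library, an alternative chosen after the data were seen.

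**Figure D2:**
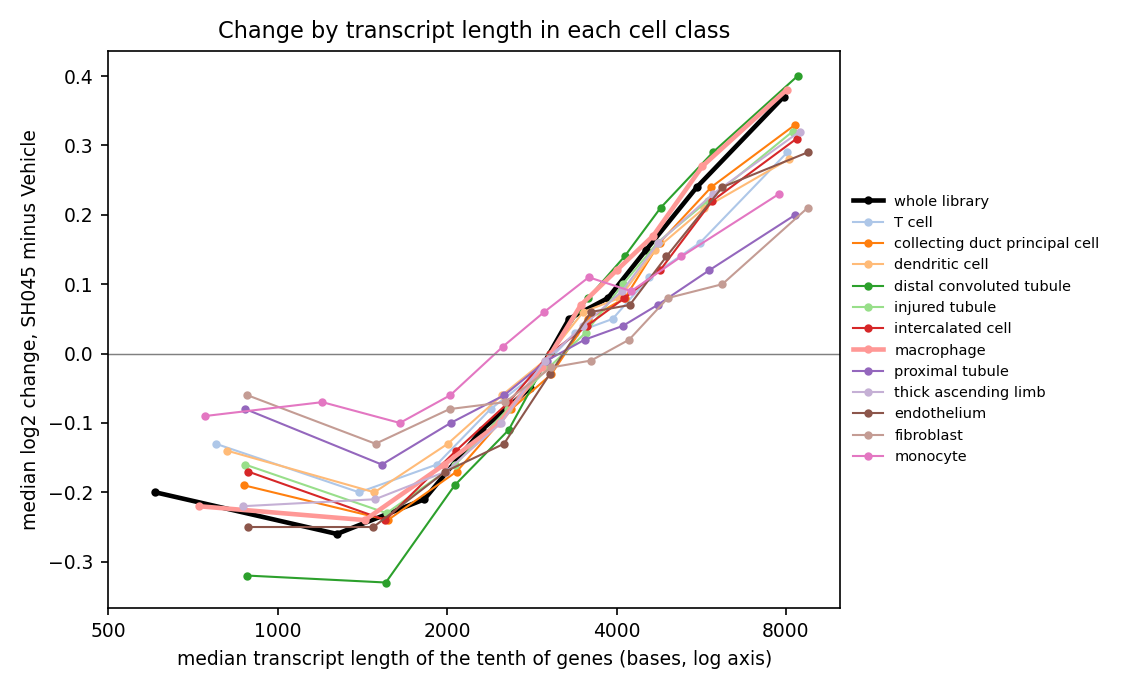
Median log2 change (SH045 minus Vehicle) in each 10% of the tested genes ordered by transcript length, with 1 line per cell class. In whole-library sums the line runs from -0.20 at a median length of 606 bases to 0.37 at 7926 bases.

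In the whole-library sums, most measured collagens and matrix genes rose with SH045, and 4 of 28 chemokines and cytokines fell (camera adjusted p = 0.000111, adjusted p = 0.316 with an estimated correlation). Col1a1 and Col3a1, chains of the fibrillar collagens of scar tissue, rose by 3.17 ± 0.34 and 2.75 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.00698 and 0.00674). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) went from 49.6 ± 15.9 to 446 ± 151 and Col3a1 (ENSMUSG00000026043) from 67.4 ± 13.6 to 452 ± 163 CPM (SD, n = 3). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), the chief attractant of blood monocytes, fell by 1.26 ± 0.13, from 183 ± 3.51 to 76.6 ± 10.7 CPM (adjusted p = 0.00602, edgeR).

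The sums over all cells combine expression with cell shares, and the fibroblast share itself differed 5.25-fold. Of 38 measured genes of collagens and matrix, 30 rose and 1 fell (34 and 1 adjusted over the list alone), with a median log2 change of 1.95 (camera adjusted p = 2.16e-58, adjusted p = 0.316 with an estimated correlation). Col6a2 and Col6a1, chains of the beaded-filament collagen VI, rose by 3.49 ± 0.18 and 3.06 ± 0.21, and Bgn, a small matrix proteoglycan, by 2.13 ± 0.17. Col11a1, a minor fibrillar collagen with 363 UMIs against 3, had a ratio of 152 (counting interval 51.5 to 739). The member that fell was Fn1, fibronectin, from 246 ± 52.4 to 116 ± 30.8 CPM, and its call ended with any 1 library left out (adjusted p from 0.0519 to 0.151). Fn1 also marked macrophage cluster 20, which was 1.98 ± 1.37% of SH045 and 7.76 ± 1.0% of Vehicle cells. Of 19 contractile and myofibroblast genes 8 rose (13 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.35e-10, adjusted p = 0.35 with an estimated correlation), among them Cald1, an actin-binding protein, by 1.09 ± 0.12 and Pdgfrb, the growth factor receptor of stromal cells, by 1.92 ± 0.22. Acta2, smooth muscle actin and the usual myofibroblast marker, was 62.6 ± 11.7 against 20.8 ± 12.6 CPM and did not pass (adjusted p = 0.098, edgeR), nor did Tgfb1 (log2 change -0.36, adjusted p = 0.331).

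Wnt and Notch genes and matrix-degrading enzymes rose in part. Of 27 Wnt and Notch genes 5 rose (18 adjusted over the list alone, camera adjusted p = 4.35e-10, adjusted p = 0.35 with an estimated correlation), among them Dkk3, a secreted member of the dickkopf family, by 1.29 ± 0.14. Of 22 genes of matrix-degrading enzymes and inhibitors 6 rose and 2 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.526 with an estimated correlation), and the list call ended without Vehicle 1 (adjusted p = 0.075, in a range from 0.0103 over the libraries left out). The gelatinases Mmp2 and Mmp9 rose by 2.16 ± 0.23 and 2.45 ± 0.24, and Plaur, the urokinase receptor, fell by 1.39 ± 0.14. Markers of neutrophils, which make much Mmp9, were 403 ± 291 against 95 ± 34.4 CPM over all barcodes with Mmp9 left out of the sum. They were unequal between the SH045 libraries, at 730, 306 and 172 CPM in SH045 1, 2 and 3. No cluster was named neutrophil, and S100a8 and Clec4d of these markers were among the top genes of the monocyte cluster. Whether neutrophils carry the rise of Mmp9 was not tested. Of 21 endothelial activation genes 7 rose (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.02e-05, adjusted p = 0.482 with an estimated correlation), beside an endothelial share that was 3.30 times higher.

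Fewer genes passed in the lists of chemokines and of antigen presentation. Of 28 chemokines and cytokines 1 rose and 4 fell (1 and 10 adjusted over the list alone), with a median log2 change of -0.44 (camera adjusted p = 0.000111, adjusted p = 0.316 with an estimated correlation). Besides Ccl2, Ccl9, a chemokine of myeloid cells, fell by 1.27 ± 0.15. Ccl9 also marked macrophage cluster 20, which was 1.98 ± 1.37% of SH045 and 7.76 ± 1.0% of Vehicle cells. Of 23 antigen presentation genes 2 fell (10 adjusted over the list alone, camera adjusted p = 3.28e-05, adjusted p = 0.705 with an estimated correlation), beside a dendritic share that was 1.86 times lower. The immunoglobulin light chain genes Igkv6-32 and Igkv6-14 had 0 UMIs with SH045 against 227 and 221 with Vehicle and were at least 60.4-fold and 58.8-fold lower (floor of 3 counts over the group). Plasma cells numbered 96, 3 and 29 in SH045 1, 2 and 3 and 52, 116 and 85 in Vehicle 1, 2 and 3. With as few as 3 cells in a library, that class was not tested for genes, so these falls cannot be told from its few cells. The call of Igkv6-14 ended without SH045 1 (adjusted p = 0.0522, in a range over its alternatives from 5.29e-09).

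In all, 668 of 16386 genes were called in the whole-library sums, 464 higher and 204 lower, and all 668 were separated between groups, as were 33.5% of the genes tested. The mean of that share over all splits of the libraries is 10%. Genes of a library move together, as with length, so 1 split can lie far from that mean. By class the share ran from 11.4% in proximal tubule to 35.5% in macrophages. Separation of called genes follows largely from the call and is no separate support. After removal of the trend on transcript length 483 were called (277 higher, 206 lower), 385 of them in both. Without SH045 1, SH045 2, Vehicle 1, Vehicle 2 or Vehicle 3 the count was 87, 277, 143, 323 or 190, and the DESeq2 test called 1930. Of the lists above, 23 collagens and matrix genes and 4 endothelial activation genes rose without the trend, and 1 antigen presentation gene and 3 chemokines and cytokines fell. The calls of Col1a1, Col3a1, Col6a1, Col6a2, Bgn, Cald1, Pdgfrb, Dkk3, Mmp2, Mmp9, Plaur, Ccl2 and Ccl9 held in each of the 6 fits with 1 library left out.

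**Figure D3:**
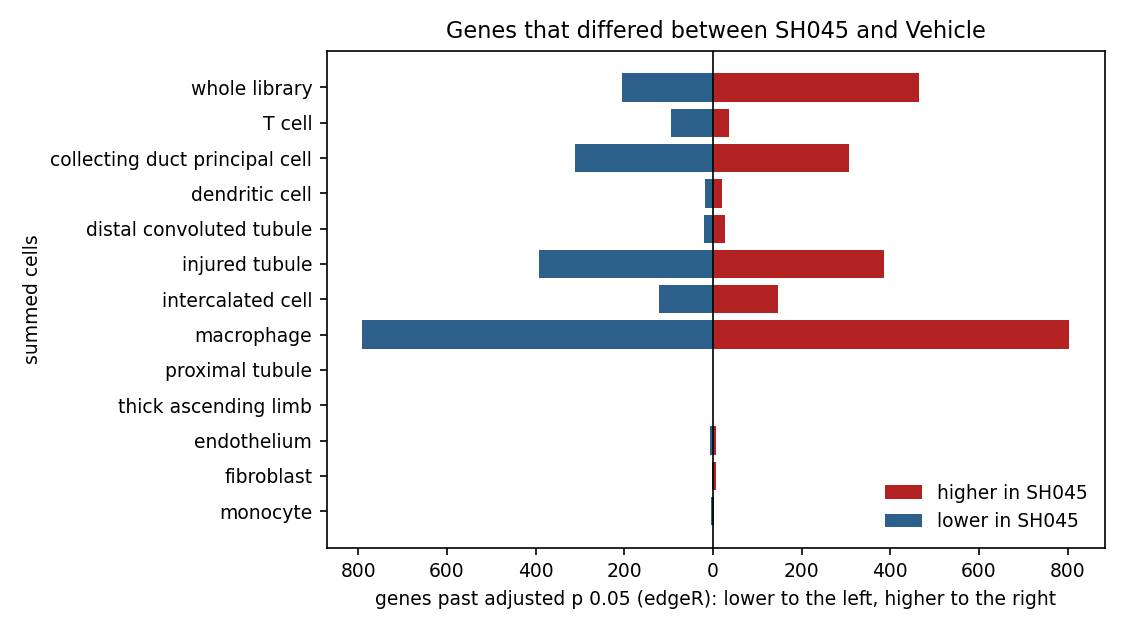
Number of genes called in each cell class by edgeR, with genes lower with SH045 to the left and genes higher to the right. The bars reach 464 higher and 204 lower genes in whole-library sums, and 0 in proximal tubule and thick ascending limb.

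In fibroblasts themselves, Col1a1 was 12000 ± 3280 against 6430 ± 1570 CPM (SD, n = 3; log2 change 0.90 ± 0.23, adjusted p = 0.2, edgeR) and Col3a1 was 12100 ± 3260 against 8970 ± 1200 (adjusted p = 0.556). Col6a2 rose by 1.38 ± 0.22 and Igf1, a growth factor of stromal cells and macrophages, by 2.86 ± 0.44, while Nkd2, an intracellular Wnt antagonist, fell by 1.46 ± 0.22, from 295 ± 44.6 to 107 ± 4.51 CPM (adjusted p = 0.0193, 0.0454 and 0.0173). Tgfb1 was 230 ± 86.5 against 548 ± 28.6 CPM (log2 change -1.26 ± 0.25) and did not pass (adjusted p = 0.064). Rbp4, the retinol carrier that fat tissue also makes, had 200 UMIs against 0 and was at least 13.5-fold higher (floor of 3 counts over the group), beside adipocyte markers of 41.9 and 44.7 CPM in SH045 1 and SH045 3. Of 38 collagens and matrix genes 1 rose (11 adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 1.77e-11, adjusted p = 0.433 with an estimated correlation), and with the length trend removed 0 passed (8 adjusted over the list alone) and the median was 0.24. In all 10 genes were called (7 higher, 3 lower), with 3 when the length trend was removed, where Col6a2 and Igf1 did not pass (adjusted p = 0.0796 and 0.124). With the Vehicle libraries holding as few as 24 fibroblasts, the count was 5, 3, 70, 0, 6 and 1 without SH045 1, 2 and 3 and Vehicle 1, 2 and 3, and the Col6a2, Igf1, Nkd2 and Rbp4 calls ended without Vehicle 1 (adjusted p = 0.266, 0.402, 0.181 and 0.181) and without Vehicle 3 (adjusted p = 0.14, 0.313, 0.14 and 0.105).

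In macrophages, 10 of 20 resident and repair macrophage genes rose and 30 of 51 oxidative phosphorylation genes fell, with the list tests given below. The cluster marked by Ccl8, Stab1, Pf4 and Mrc1 made up 32.82 ± 7.39% of SH045 and 17.66 ± 3.99% of Vehicle macrophages (SD, n = 3). The sums therefore combine changes within clusters with another mix of clusters. Stab1 (ENSMUSG00000042286, chromosome 14, 31139013 to 31168641), a scavenger receptor of tissue macrophages, rose by 1.44 ± 0.16 on the log2 scale, from 113 ± 18.1 to 308 ± 58.6 CPM (SD, n = 3, edgeR adjusted p = 0.00013). F13a1, coagulation factor XIII subunit A, rose by 1.47 ± 0.15 and Gas6, a ligand of receptors for apoptotic cell uptake, by 0.94 ± 0.13. Ccl2 fell by 0.98 ± 0.16, from 346 ± 75.9 to 176 ± 13.1 CPM (adjusted p = 0.00197). Mmp9 (ENSMUSG00000017737) rose by 5.03 ± 0.33, from 0.953 ± 0.438 to 33.8 ± 10.6 CPM.

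Of 20 measured resident and repair macrophage genes 10 rose and 0 fell (12 adjusted over the list alone, median log2 change 0.69, camera adjusted p = 1.95e-08, adjusted p = 0.316 with an estimated correlation). Lyve1, a hyaluronan receptor of perivascular macrophages, had 47 UMIs against 1, a ratio of 74.8 (counting interval 12.8 to 3020). Of 51 oxidative phosphorylation genes 30 fell and 0 rose (38 adjusted over the list alone), with a median log2 change of -0.45 (camera adjusted p = 3.56e-12, adjusted p = 0.643 with an estimated correlation). Cycs, cytochrome c, fell by 0.72 ± 0.13 and Uqcrc1, a core subunit of complex III, by 0.70 ± 0.15. Of these 51, 7 fell with the length trend removed, and the median was -0.23. Of 7 mitochondrially encoded genes, which can also follow cell or RNA quality, 1 rose in macrophages (camera adjusted p = 0.386), and 2 with the trend removed (6 adjusted over the list alone, camera adjusted p = 0.00677). Of 38 cell cycle genes 9 fell (10 adjusted over the list alone, camera adjusted p = 3.29e-05, adjusted p = 0.681 with an estimated correlation), among them Cenpa, the centromeric histone, by 0.84 ± 0.14. After removal of the length trend 5 of them fell. Of the 2 cycling clusters, the one marked by Mki67 and Top2a made up 3.41 ± 0.91% against 5.05 ± 0.36% of macrophages, and the one marked by Mcm2 and Mcm5 4.29 ± 2.38% against 4.89 ± 1.16% (SD, n = 3, exact permutation p = 0.1 and 0.7).

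Interferon and complement genes rose in part. Of 40 interferon response genes 8 rose (9 adjusted over the list alone, camera adjusted p = 0.00485, adjusted p = 0.691 with an estimated correlation), among them Oas2, a sensor of viral RNA, by 0.90 ± 0.18. Of 14 complement genes 4 rose and 1 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.482 with an estimated correlation): C4b, a component of the classical pathway, rose by 0.98 ± 0.16, while Cfp, properdin, which stabilises the convertase of the alternative pathway, fell by 0.76 ± 0.15. Both list calls ended without SH045 2 (adjusted p = 0.054 and 0.0685) and without cluster 20, the Retnla and Fn1 macrophages (adjusted p = 0.45 and 0.389, in ranges over their alternatives from 6.86e-05 to 0.691 and from 0.00108 to 0.482). S100a11, a calcium-binding protein, fell by 1.26 ± 0.17, and Rem1, a small GTPase, by 2.55 ± 0.26.

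In all 1595 of 11674 genes were called in macrophages (804 higher, 791 lower), 1575 of them separated, as were 35.5% of the genes tested, where the mean over all splits is 10%. Without the length trend 862 were called (667 in both), and 826 without cluster 20, which made up 5.33 ± 3.85% of SH045 and 17.12 ± 2.33% of Vehicle macrophages. The count was 467, 748, 528 and 425 without SH045 1, SH045 3, Vehicle 1 and Vehicle 2, and 72 with a common minimum of 3175 UMIs, where Cycs, Uqcrc1, Oas2, C4b and Cfp did not pass (adjusted p from 0.0583 to 0.0828, the highest of their alternatives). The changes of the called genes kept their size there, with a slope of 0.94 and 1570 of 1570 in the same direction, and without cluster 20 the slope was 0.84. Both sets are parts of the cells that gave the calls, so this agreement is no independent support. Stab1, F13a1, Gas6, Ccl2, Mmp9, Lyve1, Cenpa, S100a11 and Rem1 were called in each of the 6 fits with 1 library left out. Of the other neutrophil markers measured in macrophages, S100a8 had a log2 change of 0.11 ± 0.34 and S100a9 of 0.37 ± 0.37, and none passed (adjusted p = 0.862 and 0.549, with 0.0553 for Csf3r as the smallest).

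In injured tubule cells, 10 of 28 tubular injury genes and 10 of 35 cell cycle genes fell, and 9 of 39 proximal tubule genes rose, with the list tests given below. Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), which encodes the injury receptor KIM-1, fell by 0.63 ± 0.13 on the log2 scale, from 1210 ± 111 to 781 ± 96.3 CPM (SD, n = 3, edgeR adjusted p = 0.00579). Slc5a12, a lactate cotransporter of the proximal tubule, rose by 1.17 ± 0.17, from 75.9 ± 21.1 to 174 ± 23.8 CPM (adjusted p = 0.00146), and Hnf4a, the transcription factor of proximal tubule identity, by 0.74 ± 0.12. Lrp2, the endocytic receptor megalin, rose by 0.85 ± 0.14, from 270 ± 16.2 to 487 ± 94.3. Top2a, the DNA topoisomerase of dividing cells, fell by 1.16 ± 0.21, from 64.9 ± 19.7 to 28.1 ± 6.36.

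Of 28 tubular injury genes 10 fell and 0 rose (13 adjusted over the list alone, median log2 change -0.67, camera adjusted p = 1.31e-15, adjusted p = 0.35 with an estimated correlation). Anxa2, a membrane-binding annexin, fell by 1.01 ± 0.14, Il34, a ligand of the macrophage receptor Csf1r, by 0.82 ± 0.13 and Sox9, a transcription factor of regenerating tubule, by 0.79 ± 0.14. Of 35 cell cycle genes 10 fell and 0 rose (18 adjusted over the list alone, median -1.16, camera adjusted p = 6.05e-19, adjusted p = 0.482 with an estimated correlation). Of 39 genes of proximal tubule transport and metabolism 9 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.000107, adjusted p = 0.631 with an estimated correlation), and without Vehicle 3 the adjusted p was 0.0511.

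Of 29 early response and dissociation stress genes 7 fell (9 adjusted over the list alone, camera adjusted p = 8.42e-08, adjusted p = 0.482 with an estimated correlation), among them Ier2, an immediate early gene, by 1.04 ± 0.13. Of 24 apoptosis and senescence genes 5 fell (6 adjusted over the list alone, camera adjusted p = 0.000448, adjusted p = 0.35 with an estimated correlation), among them Bax, which permeabilises mitochondria, by 0.62 ± 0.11 and Phlda3, a target of p53, by 1.16 ± 0.20. Of 21 chemokines and cytokines 5 fell (8 adjusted over the list alone, camera adjusted p = 4.39e-05, adjusted p = 0.354 with an estimated correlation). Once the length trend was removed, 5 tubular injury, 4 cell cycle, 1 early response, 3 apoptosis and senescence and 3 chemokine and cytokine genes fell and 6 proximal tubule genes rose. Mitochondrially encoded genes, which can also follow cell or RNA quality, rose in the same class, 2 of 7 (5 adjusted over the list alone, camera adjusted p = 0.000578, adjusted p = 0.568 with an estimated correlation), and 3 of 7 (7 adjusted over the list alone) once the trend was removed. Pkm, pyruvate kinase, fell by 1.34 ± 0.17. Among the largest falls were Igfbp2, which binds insulin-like growth factors, by 4.29 ± 0.62, Adgra1, an adhesion receptor, by 3.01 ± 0.45 and Wnt10a, a Wnt ligand, by 2.90 ± 0.48. Angpt1, the ligand of the endothelial receptor Tek, rose by 1.62 ± 0.34. Lcn2 (log2 change -1.55 ± 0.66, adjusted p = 0.261) and Vcam1 (log2 change -0.17) did not pass.

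In all 777 of 10833 genes were called in injured tubule (385 higher, 392 lower), 766 of them separated, as were 28.2% of the genes tested, where the mean over all splits is 10%. With the length trend removed 315 were called (250 in both), and Havcr1 and Lrp2 did not pass (adjusted p = 0.0567 and 0.0779, log2 changes -0.45 and 0.49). The count was 221, 480 and 350 without SH045 1, SH045 3 and Vehicle 2. With cells named singly Havcr1, Sox9, Il34 and Top2a did not pass (adjusted p = 0.188, 0.424, 0.0589 and 0.62, the highest of their alternatives, whose lowest were 9.17e-05, 5.04e-05, 1.42e-06 and 3.79e-08), and Top2a did not pass without doublet removal (adjusted p = 0.181). Slc5a12, Hnf4a, Anxa2, Ier2, Bax, Phlda3, Pkm, Igfbp2, Adgra1, Wnt10a and Angpt1 were called in every alternative run.

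**Figure D4:**
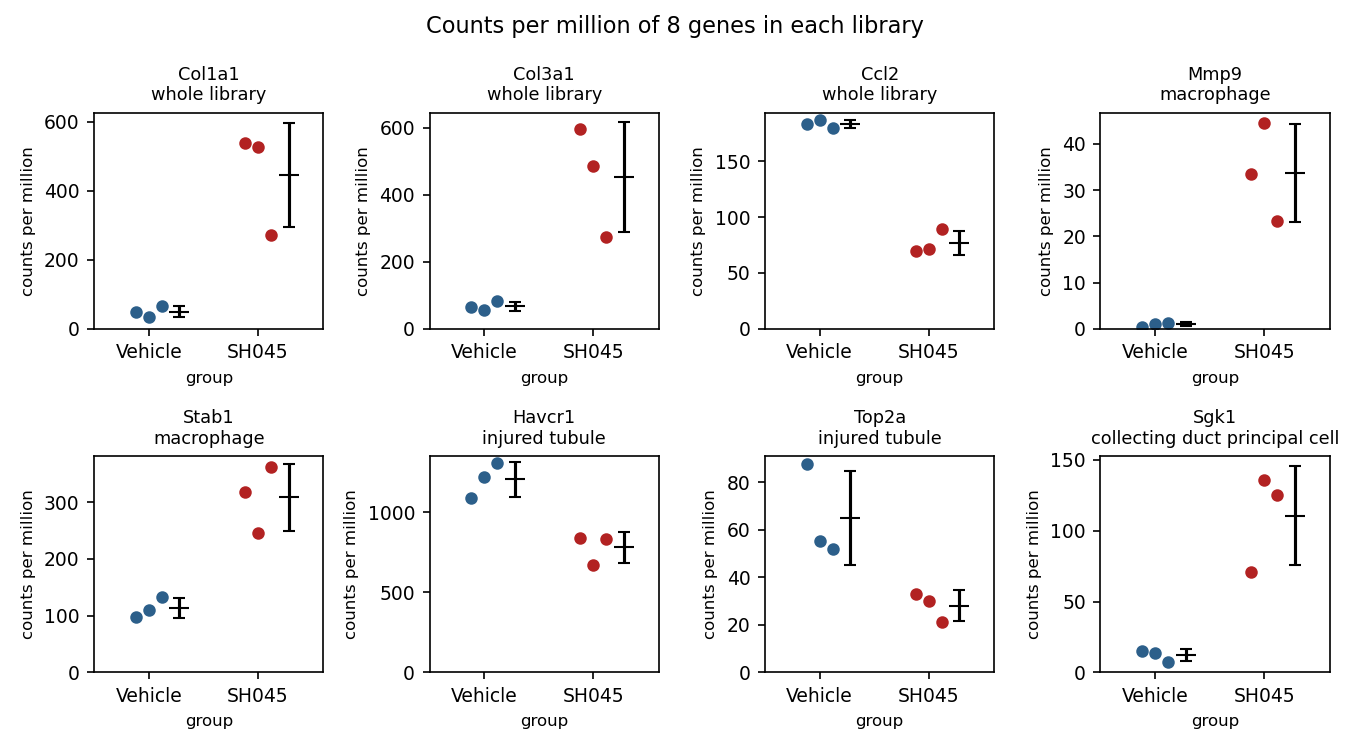
CPM of 8 genes in the whole library, macrophages, injured tubule and collecting duct principal cells, with 1 dot per library (n = 3 SH045, n = 3 Vehicle) and the mean with SD. In each panel all SH045 libraries lie on the same side of all Vehicle libraries.

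Proximal tubule cells outside the injured class showed no called gene. Havcr1 had a log2 change of -0.13 ± 0.60, Lrp2 of 0.33 ± 0.23 and Slc34a1, the phosphate transporter of the healthy proximal tubule, of 0.10 (SE, n = 3). The same holds for the thick ascending limb, the salt-reabsorbing segment, where 51 oxidative phosphorylation genes had a median log2 change of -0.33 with 0 called (camera adjusted p = 3.01e-10, adjusted p = 0.681 with an estimated correlation), and of -0.13 with the length trend removed (camera adjusted p = 0.00209). The edgeR test called 0 genes in proximal tubule, against 472 of 9135 at an unadjusted p under 0.05 and 7 by DESeq2, and 0 in thick ascending limb, against 909 of 7720 and 0 by DESeq2. With no change at all, a share of 0.05 of the genes is expected under that unadjusted limit. The proximal tubule number lay near that share and the thick ascending limb number above it. Without SH045 3 the proximal tubule count was 10, and without Vehicle 2 or Vehicle 3 the thick ascending limb count was 2 or 1. A difference in response between these classes and the injured tubule was not tested.

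In collecting duct principal cells, which reabsorb sodium and water, Sgk1 rose most. Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903), a kinase induced by aldosterone and glucocorticoids that raises sodium channel activity, rose by 3.22 ± 0.30 on the log2 scale, from 12.2 ± 4.25 to 111 ± 35 CPM (SD, n = 3, edgeR adjusted p = 3.09e-05). Ndrg1, a gene induced by hypoxia, rose by 1.39 ± 0.15, from 242 ± 24.6 to 630 ± 72.7 (adjusted p = 1.7e-05). Cdkn1a, the cell cycle inhibitor p21, fell by 0.99 ± 0.15 and Ltbp2, a matrix protein of elastic fibres, by 3.44 ± 0.58.

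Of 24 glycolysis and hypoxia genes 4 rose (5 adjusted over the list alone, camera adjusted p = 0.00485, adjusted p = 0.35 with an estimated correlation). Of 27 cell cycle genes 7 fell (12 adjusted over the list alone, median log2 change -1.08, camera adjusted p = 1.09e-13, adjusted p = 0.526 with an estimated correlation), and of 25 tubular injury genes 5 fell (6 adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.405 with an estimated correlation). Of 13 collagens and matrix genes 4 fell (8 adjusted over the list alone, camera adjusted p = 9.92e-05, adjusted p = 0.526 with an estimated correlation), a list call that ended with no low-count filter (adjusted p = 0.0951, in a range from 6.24e-08 to 0.526). Once the length trend was removed, 3 cell cycle and 2 tubular injury genes fell. Plau, urokinase, fell by 1.05 ± 0.19, Tnfrsf12a, the receptor of the cytokine TWEAK, by 0.92 ± 0.15, and Fgf18, a fibroblast growth factor, by 2.95 ± 0.59. Of 19 antigen presentation genes 3 fell (1 rose and 10 fell adjusted over the list alone, camera adjusted p = 2.93e-05, adjusted p = 0.536 with an estimated correlation), beside class II transcripts of 520 ± 35.7 against 1268 ± 490 CPM in this class. Cd74, the invariant chain, fell by 1.36 ± 0.22, a call that ended without Vehicle 1 (adjusted p = 0.0754) and with cells named singly (adjusted p = 0.737, in a range over its alternatives from 1.37e-13).

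In all 618 of 10538 genes were called (307 higher, 311 lower), 608 of them separated, as were 27.7% of the genes tested, where the mean over all splits is 10%. Free of the length trend, 446 were called (328 in both). The count was 340, 311 and 262 without SH045 1, SH045 3 and Vehicle 3, and 312 with cells named singly. Sgk1, Ndrg1, Cdkn1a, Ltbp2, Plau, Tnfrsf12a and Fgf18 were called in every alternative run.

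In intercalated cells, which secrete acid or base, Fgg rose and interferon-induced GTPases fell. Fgg, the gamma chain of fibrinogen, rose by 2.98 ± 0.19 on the log2 scale, from 29 ± 2.71 to 229 ± 56.4 CPM (SD, n = 3, edgeR adjusted p = 1.6e-14). Igfbp5, which binds insulin-like growth factors, rose by 2.26 ± 0.31. Igtp, Iigp1 and Ifi47, GTPases that interferon-gamma induces against intracellular microbes, fell by 1.65 ± 0.28, 1.48 ± 0.26 and 1.37 ± 0.28. Of 21 interferon response genes these 3 fell (4 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.681 with an estimated correlation), a list call that ended without SH045 2, SH045 3 or Vehicle 3 (adjusted p = 0.0743, 0.0802 and 0.0511). Of 18 antigen presentation genes 3 fell (9 adjusted over the list alone, camera adjusted p = 1.95e-11, adjusted p = 0.35 with an estimated correlation), with 1 after removal of the length trend, beside class II transcripts of 597 ± 152 against 1260 ± 384 CPM in this class. In all 268 of 9354 genes were called (147 higher, 121 lower), with 145 when the length trend was removed (104 in both). The count was 77, 108, 99 and 475 without SH045 1, SH045 3, Vehicle 2 and Vehicle 3, and 132 at a mitochondrial limit of 20%.

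In the distal convoluted tubule, 28 genes rose and 20 fell. Fgg rose by 1.76 ± 0.24, and Atp6v1g3 and Aqp6, a proton pump subunit and a water channel that mark intercalated cells, by 2.32 ± 0.33 and 3.68 ± 0.65. C1qc, a complement chain made by macrophages, fell by 1.88 ± 0.27, and of 18 antigen presentation genes 4 fell (10 adjusted over the list alone, camera adjusted p = 7.34e-12, adjusted p = 0.35 with an estimated correlation), with 2 after removal of the length trend. Class II transcripts were 526 ± 156 against 1930 ± 813 and C1q transcripts 85.3 ± 35.9 against 247 ± 93.4 CPM in this class (SD, n = 3). These calls of Fgg, Atp6v1g3, Aqp6 and C1qc ended with cells named singly (adjusted p = 0.37, 0.471, 0.47 and 0.502, the highest of their alternatives), and Aqp6 also ended without SH045 3 or Vehicle 3 (adjusted p = 0.106 and 0.064). The count of 48 became 19 with the length trend removed, 5 with cells named singly, and 9, 8, 85, 91 and 25 without SH045 1, SH045 3, Vehicle 1, Vehicle 2 and Vehicle 3.

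In T cells, Klri2, a receptor of the killer lectin-like family, rose by 2.10 ± 0.35 on the log2 scale, from 14.9 ± 4.5 to 58.8 ± 22.2 CPM (SD, n = 3, edgeR adjusted p = 0.00049). Also higher was mt-Nd5, a mitochondrially encoded complex I subunit, by 1.08 ± 0.19. Eomes, a transcription factor of cytotoxic lymphocytes, rose by 1.98 ± 0.36, a call that ended with cells named singly (adjusted p = 0.059, in a range from 2.09e-07). No cluster was named natural killer, a class of the marker table, and the T cell cluster had Nkg7, Xcl1 and Ctsw among its top genes. The class may therefore hold such cells, and a shift between the 2 kinds was not tested. Among the 94 genes that fell was Cd209a, a lectin of dendritic cells, by 3.83 ± 0.45, and of 7 complement genes 5 fell (6 adjusted over the list alone, camera adjusted p = 9.96e-12, adjusted p = 0.316 with an estimated correlation). Class II transcripts in this class were 6867 ± 828 against 20006 ± 5577 CPM, and C1q transcripts, which macrophages make, 1219 ± 239 against 2896 ± 750 CPM. Whether these falls belong to the T cells, or to free RNA or immune cells caught in the same droplets, was not tested. In all 131 of 7130 genes were called, with 125 when the length trend was removed (104 in both), 67 without Vehicle 3, 49 without doublet removal and 51 at the common UMI minimum.

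In dendritic cells 37 of 8849 genes were called, 20 higher and 17 lower, with 28 when the length trend was removed. Ccr9, a chemokine receptor of plasmacytoid dendritic cells, rose by 2.13 ± 0.31 on the log2 scale, from 11.9 ± 4.8 to 52.0 ± 16.7 CPM (SD, n = 3, edgeR adjusted p = 0.0107), and did not pass at a mitochondrial limit of 20% (adjusted p = 0.119, in a range from 2e-13). The cluster marked by Siglech and Ccr9 made up 5.85 ± 0.63% of SH045 and 1.70 ± 0.94% of Vehicle dendritic cells. Ccl3, an inflammatory chemokine, fell by 1.26 ± 0.21, a call that ended without SH045 3 or Vehicle 1 (adjusted p = 0.0541 and 0.0743). The count was 21, 15, 11 and 9 without SH045 1, SH045 3, Vehicle 1 and Vehicle 3, and 3 at the common UMI minimum.

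In endothelial cells 15 genes were called and in monocytes 6, with 13 (6 in both) and 7 (4 in both) when the length trend was removed. Endothelial Nr2f2, the transcription factor of venous identity, rose by 1.38, and Fabp5, a fatty acid binding protein, by 1.90, at an adjusted p = 0.0246 and 0.0205 (edgeR, n = 3). Both calls ended without SH045 3 (adjusted p = 0.101 and 0.124) and without Vehicle 1 (adjusted p = 0.0645 for each). Of 19 endothelial activation genes 0 passed in endothelial cells, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.545 with an estimated correlation), a list call that ended without SH045 3, Vehicle 2 or Vehicle 3 (adjusted p = 0.0531, 0.0623 and 0.126). In monocytes Ccl7, a chemokine that attracts monocytes, fell by 3.01, and Ctsl, a lysosomal protease, rose by 2.31, and both ended with cells named singly (adjusted p = 0.839 and 0.482, the highest of their alternatives). The endothelial count was 7, 2, 6, 32 and 36 without SH045 2, SH045 3, Vehicle 1, Vehicle 2 and Vehicle 3, and the monocyte count 20, 17 and 36 without SH045 1, 2 and 3.

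Across the 9 classes and the whole-library sums, 99 of 263 pairs of list and class passed camera, 0 of them with an estimated correlation (smallest adjusted p = 0.316) and 18 pairs passed fry. With the length trend removed 87 passed, and 69 of the 99 passed in the same direction. A split of the libraries that put SH045 1, SH045 2 and Vehicle 1 against the rest gave 105.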

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

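The tests of the fibroblast share outside macrophages and dendritic cells, of the common UMI minimum, of the distal tubule and collecting duct classes (also against the level of the library) and of the splits of the gene counts were chosen only after the results were seen. Barcodes over the mitochondrial limit made up 12.4% of SH045 and 4.34% of Vehicle barcodes and were left out of all comparisons but those over all deposited barcodes, where whole-library sums called 766 genes. There were 20 genes called higher in 1 class and lower in another, among them Spp1, osteopontin, with a log2 change of -0.76 in injured tubule and 1.14 in intercalated cells, and the difference between classes was not tested.

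Fibroblasts and endothelial cells took larger shares of the SH045 libraries. A lower share of macrophages and dendritic cells could raise all other shares, but with these and monocytes left out of the total the fibroblast ratio was still 3.88, which argues against it as the whole cause. Depth of the barcodes could matter, but with a common UMI minimum the ratio was 5.28. Whether tissue from around the kidney entered the SH045 samples stays open: fibroblasts with no UMI of 6 adventitial genes had a ratio of 3.74, over the bound of 2 set beforehand, but this decides nothing because, of SH045 fibroblasts with a UMI of Dpt, only 50.8% had one of another of these genes (65.8% for Mfap5, and 93% to 100% for the other 4), and fibroblasts with such a UMI had a ratio of 6.85. Adipocyte markers were at 41.9 and 44.7 CPM in SH045 1 and SH045 3 but 0.121 in SH045 2, and the explanation was not tested for endothelium. SH045 2 was not free of such transcripts. Adipoq, an adipocyte marker, had 20, 3 and 196 UMIs in SH045 1, 2 and 3 and 0 in each Vehicle library. Of SH045 2 fibroblasts, 76.4% had a UMI of the adventitial genes, the highest of the libraries.

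Many genes changed in the macrophage class. Another mix of macrophage clusters could account for part. Changes were taken here as differences of mean log2 CPM with a prior count of 2, with each cluster given equal weight. For the called genes they had a slope of 0.52 on the same measure of the pooled clusters (0.47 to 0.55 leaving out a library). Of 1595 called genes, 1541 kept their direction. The prior count draws changes in small clusters toward 0, and 1 cluster held 25 cells in SH045 1. That lowers the slope as well, which therefore cannot tell between a mix and a change within clusters. Transcript length might carry the changes, and with the length trend removed the slope was 0.86 (0.84 to 0.89). That slope weights the largest changes, while median changes by length ran only from -0.24 to 0.38. It argues against length as the whole cause of the largest changes, and says little about the smaller ones. The count went from 1595 to 862, with 667 called in both. What stays open is why the trend on length follows the groups in these libraries. It could be a property of RNA quality or of library preparation, and the share of barcodes over the mitochondrial limit, 12.4% with SH045, also follows the groups.

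Over all tubule classes together, class II transcripts had a ratio of SH045 to Vehicle of 0.64, with libraries apart, and C1q transcripts of 0.67, overlapping (exact permutation p = 0.1 and 0.3), and by class the 2 ratios were 0.27 and 0.35 in distal convoluted tubule, 0.41 and 0.62 in collecting duct principal cells, 0.47 and 0.81 in intercalated cells, 0.69 and 1.07 in thick ascending limb, 0.77 and 0.46 in injured tubule and 0.97 and 1.57 in proximal tubule. Free RNA from macrophages and dendritic cells would carry class II and C1q transcripts in the ratio of the library. Over all tubule classes that ratio was 2.32 times the ratio of the library, which argues against free RNA as the whole source of these transcripts there. It does not decide where the fall with SH045 comes from, because it pools unlike classes. Injured tubule alone held class II at 4566 ± 504 and C1q at 62.3 ± 10.9 CPM with SH045. In the distal tubule and collecting duct classes alone the ratio was 0.88 times that of the library, as free RNA or immune cells caught in the same droplets would give. An equal part of free RNA in each library would however fall only as the library does (ratios of 0.58 for class II and 0.91 for C1q), and against the library these classes held 2.02 ± 0.224% with SH045 and 2.80 ± 0.414% with Vehicle of its class II level, and 2.22 ± 0.256% and 3.31 ± 0.39% of its C1q level. Whether the falls of class II genes in those classes belong to the tubule cells stays open.

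The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. In whole-library sums the real split called 668 genes and the highest other 0, so the real split alone, 1 of the 10, reached that count. The real and highest other counts were 1595 and 0 in macrophages, 777 and 1 in injured tubule, 618 and 1 in collecting duct principal cells, 268 and 1 in intercalated cells, 131 and 1 in T cells, 48 and 2 in distal convoluted tubule, 37 and 6 in dendritic cells, 15 and 10 in endothelium, 10 and 2 in fibroblasts and 6 and 1 in monocytes. In proximal tubule the real split called 0 and the split of SH045 1, SH045 2 and Vehicle 1 against the rest called 59. Another grouping of the same libraries thus gave more calls than the treatment, for a cause that was not tested. In thick ascending limb the real split called 0 and the highest other 7, and in both of these classes 10 of the 10 splits called as many as the real one. For pairs of list and class, 2 of the 10 splits, the real one included, called at least 99. The split of SH045 1, SH045 2 and Vehicle 1 called 105, so the list calls do not stand apart from another grouping of the same libraries.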

How the results depend on the processing

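The common UMI minimum, the sums without cluster 20, the removal of the length trend and the edgeR fits of cell counts with a library left out were chosen only after the results were seen. With 3 mice per group the exact test cannot go under 0.1, the classes are rebuilt from markers, and the replicate numbers were not taken to pair the libraries. Over all cells the correlations of same-numbered libraries were 0.039, 0.132 and 0.281, not all over 0.1, and 4 of 6 libraries, not all, correlated best with the library of their own number, which is a hint from the data and leaves a partial pairing open. The cause of each shift below was not tested.

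Counts of called genes moved by over 1.5 times as follows. With the DESeq2 test: 1930 in whole-library sums, 399 in collecting duct principal cells, 146 in distal convoluted tubule, 488 in injured tubule, 164 in intercalated cells, 7 in proximal tubule, 28 in endothelium, 37 in fibroblasts and 11 in monocytes. With DESeq2 size factors: 6 in fibroblasts. With no low-count filter: 1304 in whole-library sums, 256 in dendritic cells, 302 in distal convoluted tubule, 33 in proximal tubule, 32 in thick ascending limb, 94 in endothelium, 157 in fibroblasts and 50 in monocytes. With a block on the replicate number: 241 in collecting duct principal cells, 15 in dendritic cells, 10 in proximal tubule, 3 in thick ascending limb, 71 in endothelium, 19 in fibroblasts and 41 in monocytes. With cells named singly: 74 in T cells, 312 in collecting duct principal cells, 5 in distal convoluted tubule, 475 in injured tubule, 556 in macrophages, 1 in proximal tubule, 4 in thick ascending limb and 45 in endothelium. With the common UMI minimum: 51 in T cells, 3 in dendritic cells, 172 in intercalated cells, 72 in macrophages, 5 in fibroblasts and 1 in monocytes. Adjusted over all classes: 112 in dendritic cells, 182 in distal convoluted tubule, 810 in macrophages, 17 in proximal tubule and 52 in thick ascending limb. With the length trend removed: 19 in distal convoluted tubule, 315 in injured tubule, 145 in intercalated cells, 862 in macrophages and 3 in fibroblasts. At a mitochondrial limit of 20%: 132 in intercalated cells and 5 in fibroblasts. With no doublets removed: 49 in T cells. Without cluster 20: 826 in macrophages.

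With 1 library left out, the count ranged from 87 (without SH045 1) to 521 in whole-library sums, 67 (without Vehicle 3) to 132 in T cells, 262 (without Vehicle 3) to 555 in collecting duct principal cells, 9 (without Vehicle 3) to 37 in dendritic cells, 8 (without SH045 3) to 91 (without Vehicle 2) in distal convoluted tubule, 221 (without SH045 1) to 684 in injured tubule, 77 (without SH045 1) to 475 (without Vehicle 3) in intercalated cells, 425 (without Vehicle 2) to 2193 in macrophages, 0 to 10 (without SH045 3) in proximal tubule, 0 to 2 (without Vehicle 2) in thick ascending limb, 2 (without SH045 3) to 36 (without Vehicle 3) in endothelium, 0 (without Vehicle 1) to 70 (without SH045 3) in fibroblasts and 6 to 36 (without SH045 3) in monocytes. For pairs of list and class the range was 88 to 120 around 99, with 0 at an estimated correlation and 18 by fry.

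Log2 ratios of shares turned direction, among others, for erythroid cells without Vehicle 1 (4.248, range from -2.474), monocytes without SH045 1 (-0.606, range to 0.69), proximal tubule without Vehicle 1 (0.191, range from -1.167), pericytes and smooth muscle without SH045 1 (-0.173, from 0.154), thick ascending limb, near 0 at 0.014, without SH045 1, Vehicle 1 or Vehicle 3 (-0.144, -0.256 and -0.226) and injured tubule with cells named singly (-0.074). With edgeR on cell counts the same left-out fits gave 3.584 for erythroid cells (range from -2.506), -0.611 for monocytes, 0.189 for proximal tubule, -0.16 for pericytes and smooth muscle and -0.148, -0.257 and -0.227 for thick ascending limb. The shares of fibroblasts (2.387), endothelium (1.72) and dendritic cells (-0.895) passed with edgeR on cell counts, and that of fibroblasts also with a replicate block (2.366), where endothelium and dendritic cells had an adjusted p = 0.0564 and 0.272.

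Log2 changes of single genes turned direction as follows. With cells named singly: C3 in distal convoluted tubule 0.27, Vcam1 in injured tubule 0.06, Ccl5 1.02, Nfkbia 0.31, Vcam1 0.92 and Fn1 -1.19 in proximal tubule, and Maf in endothelium -0.12. With no doublets removed: Fn1 in dendritic cells 0.53 and Ccl5 in proximal tubule 0.09. With the length trend removed: Notch2 in macrophages -0.01 and Fn1 in fibroblasts -0.12. With a library left out: Lcn2 in whole-library sums 0.17 (without Vehicle 2, range from -0.73), Vcam1 -0.22 and Lrp2 0.59 in whole-library sums (without Vehicle 1, Lrp2 range from -0.45), Vcam1 in injured tubule 0.07 (without Vehicle 3, range from -0.35), Lrp2 in macrophages -0.17 (without SH045 1, range to 0.85), Spp1 in proximal tubule -0.30 (without SH045 3, range to 0.80), Vcam1 in fibroblasts 0.18 (without Vehicle 1, range from -0.96) and Ctsd in monocytes -0.02 (without SH045 2, range to 0.84).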

Other observations

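The tests in this part were chosen only after the results were seen. Within macrophages, the cluster marked by Ccl8, Stab1, Pf4 and Mrc1, genes of tissue-resident cells, made up 32.82 ± 7.39% of SH045 and 17.66 ± 3.99% of Vehicle macrophages (SD, n = 3). Cluster 20, marked by Retnla, Mmp12 and Ear2, genes of alternatively activated macrophages, was 1.98 ± 1.37% of all SH045 and 7.76 ± 1.00% of all Vehicle cells. Within dendritic cells, the cluster marked by Cd209a and Ccl17 was 37.41 ± 5.55% with SH045 and 51.64 ± 7.59% with Vehicle. Of all non-tubule cells, T cells were 10.73 ± 4.14% against 5.42 ± 1.44%.

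Summed over all barcodes, podocyte markers were at 33.7 ± 4.53 against 21.1 ± 1.55 and Schwann cell markers at 3.05 ± 0.538 against 1.19 ± 0.369 CPM (SD, n = 3). Of the other TRPC channel genes, Trpc1 had a UMI in 470 of 22396 cells (2.1%) and Trpc5 in 24.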
